A study of Mus musculus with 18 samples.

How the data were processed

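RNA was sequenced from cells of the mammary glands of 6 nulliparous MMTV-Cre mice, 12 weeks of age. Per the labels' protocols, glands were digested with collagenase, hyaluronidase, DNase, dispase and trypsin, and cells were sorted by flow cytometry on CD49f, CD61, EpCAM and the lineage antigens CD31, CD45 and Ter119. Complementary DNA was made from 2 ng of total RNA with the Smart-Seq v4 low-input kit, and libraries from 150 pg of cDNA with Nextera XT, which does not mark the strand. The titles give each library a population (basal, AP or HSL) and a sample number from 1 to 6, which is the grouping used here.

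The authors deposited whole-number gene counts for each library, per the file headers, with 52636 gene identifiers in each file. The genome build was GRCm38 per the submitters' processing notes, and the aligner and counting tool are not given in the sources used here. Of the identifiers 52489 matched the GENCODE M21 annotation, from which symbols and coordinates were taken, and 147 did not; these hold between 0.00303 and 0.00677% of counts per library and were left out. The RPKM values that the authors deposited beside the counts, per the file headers, were used only to check the files: the summed gene counts were 87.01 to 89.88% of the library total that the RPKM values imply. The gene widths in the files equal the genomic span, introns included, for 44954 identifiers (85.6%).

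The values show how overlapping genes were treated. Of 1288 protein-coding genes whose whole span is shared with another gene, 1146 (89%) are at 0 in all libraries, against 2707 of 12178 (22.2%) with no overlap and 287 of 8430 (3.4%) with a partial one. Csn3, Muc15 and Elf3 are among those listed at 0, as is the non-coding Xist, which is not evidence that they were not expressed. Levels of genes that share part of their span are uncertain for the same reason. Of the genes given with a fold or a level in the report, Csn3 aside, Tagln shares 58% of its span, Dll1 19.7%, Il17b 17.5%, Agtr1a 14.7%, Prlr 13.8% and Itga6 11.4%, and each of the others 10% or less.

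Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the population as group and a minimum count of 10, which left 16497, and scaled with TMM factors. A robust quasi-likelihood model with 1 mean per population was fitted to all 18 libraries, and each pair of populations was compared with the quasi-likelihood F test and Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05, and counts with a fold of at least 2 are given beside the calls. Fold changes are positive where the first-named population is higher. On simulated counts with known changes in 50 genes per fold size, a 2-fold change was called in 50% of genes for AP against basal, 44% for HSL against basal and 46% for HSL against AP, and a 4-fold change in 84, 74 and 88%; of the calls 0.8, 2.52 and 3.2% were false. Few genes were changed in the simulation, all from a mean shared by the populations, whereas 39.9 to 58.4% of genes were called in the data. The simulated rates need not carry over to these comparisons. Python 3.11.15 with pandas 2.3.3 was used to read and join the tables.

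The design, the 30 gene lists, the alternatives and the rule for naming genes were set before the data were examined. Lists were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, with an estimated correlation and fry as alternatives, adjusted over all lists and comparisons. Some genes are members of several lists, so results of such lists are not independent. Shared members link the hormone-sensing and steroid hormone lists, the pan-luminal and tight junction lists, and the basal and smooth muscle lists, among others. With an estimated correlation 5 lists kept their call in AP against basal, 5 in HSL against basal and 3 in HSL against AP, of 14, 14 and 11. The list of 5 sort gate genes gave an adjusted p = 0.493 for AP against basal, 0.227 for HSL against basal and 0.274 for HSL against AP. Named genes were the 10 with the largest folds in each direction among genes called, at 50 CPM or more in the higher population and with no overlap between libraries; all gate genes; up to 4 called members with the smallest adjusted p of each marker and pathway list, and up to 2 members not called where the list gave no call or went the other way; and the 2 most abundant members of each quality and other cell type list. Not every gene the rule allows is printed: among those allowed, genes whose call held under the alternatives were preferred, after the values were seen. Genes of sample 1 given library by library in the closing section, the 12 hormone-sensing markers, and the alternatives stated there as added were chosen after their values were seen.

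The same sample number was given to 1 library of each population. Deviations from the population means correlated between libraries of the same number with r from 0.13 to 0.63 over all 18 pairs, across genes, and 17 of 18 libraries correlated best with their own number, so the numbers were taken to pair the libraries. The model without the number was set as the main one, and the number as a block was an alternative. Libraries of a population differed by more than sampling noise, with a chi-square per degree of freedom of at least 49.5, so none was a duplicate of another.

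Alternatives were DESeq2 1.42.0, limma-voom, RLE factors, total counts alone, TMM without the 100 most abundant genes, no filter, a filter of 10 CPM in 6 libraries, leaving out genes that share a large part of their span, only the 12 libraries compared, the block, samples 1 to 3 or 4 to 6 alone, each sample number or library left out, and a test against a fold of 1.5. Milk protein shares were compared with exact two-sided permutation tests. Intervals are 95% Wilson intervals; these and the floor of 3 counts, which is 0.0329 to 0.113 CPM in these libraries, cover counting error only, since the libraries carry no molecular identifiers.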

Results

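Gene counts were taken from 18 RNA sequencing libraries of the mouse mammary gland. Cells of 6 numbered samples, from 6 nulliparous animals aged 12 weeks and carrying an MMTV-Cre transgene, were sorted into 3 epithelial populations, with 6 libraries in each. Basal cells (CD49f high, CD61 positive) are the outer, contractile layer of the ducts. Alveolar progenitors, called AP here and also known as luminal progenitors, were CD49f low and CD61 positive. Hormone-sensing luminal cells, called HSL here and also known as mature luminal cells, were CD49f low and CD61 negative. Total gene counts per library ranged from 29899462 to 91095830 in basal, from 37391691 to 62505465 in AP and from 26516293 to 52404937 in HSL libraries. Levels are given as CPM (counts scaled to library size with TMM factors), mean ± SD over 6 libraries, and fold changes as log2 ± standard error. Adjusted p-values are from the quasi-likelihood test of edgeR with Benjamini-Hochberg adjustment over 16497 genes, unless a gene list is named, in which case they are from camera.

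The populations were the main source of variation. The first principal component held 55.8% of the variance of log2 CPM and the second 15.6%. Within a population the median Spearman correlation between libraries, taken across genes, was 0.976 in AP, 0.978 in basal and 0.979 in HSL. Between populations it was 0.924 for AP and HSL, 0.861 for AP and basal and 0.813 for basal and HSL. The third component, with 7.8% of the variance, set the 3 libraries of sample 1 (scores 76.13, 89.32 and 90.90) apart from the other 15, whose scores ran from -54.90 to 19.53. When each sample number in turn was given its own term beside the population, 4579 genes were called for sample 1 and between 1 and 89 for each of the other 5. This model took the 3 libraries of a number as independent, although libraries of the same number were correlated, so the counts can be too high. The models for the other 5 numbers left sample 1 in the spread, which can lower their counts.

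Transcripts of the sorting antigens followed the gates. Itga6, which encodes CD49f, stood at 670 ± 118 CPM in basal, 215 ± 21.9 in AP and 274 ± 72.3 in HSL libraries. Itgb3, which encodes CD61, stood at 97.6 ± 18, 44.6 ± 23.3 and 0.734 ± 0.508 CPM, so that HSL libraries were lower than AP libraries by a log2 fold change of -5.89 ± 0.49 (adjusted p = 1.77e-07), and by -6.52 without sample 1. Epcam, which encodes the epithelial adhesion molecule EpCAM, was at 540 ± 184 CPM in basal, 3538 ± 1310 in AP and 3086 ± 602 in HSL libraries. Pecam1 (CD31), an endothelial antigen used for exclusion, was at 44.9 ± 19, 12.7 ± 4.79 and 9.49 ± 3.21 CPM. Ptprc (CD45), the leukocyte antigen, was at 7.36 ± 5.79, 3.16 ± 4.3 and 4.25 ± 6.75 CPM. As genes of the gate, these describe the sort and are not findings between the populations. Itga6 and Itgb3 are also members of the integrin list, Epcam of the pan-luminal, Pecam1 of the endothelial and Ptprc of the leukocyte list. The counts and tests of those lists below include them, and so partly restate the sort.

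**Figure D1:**
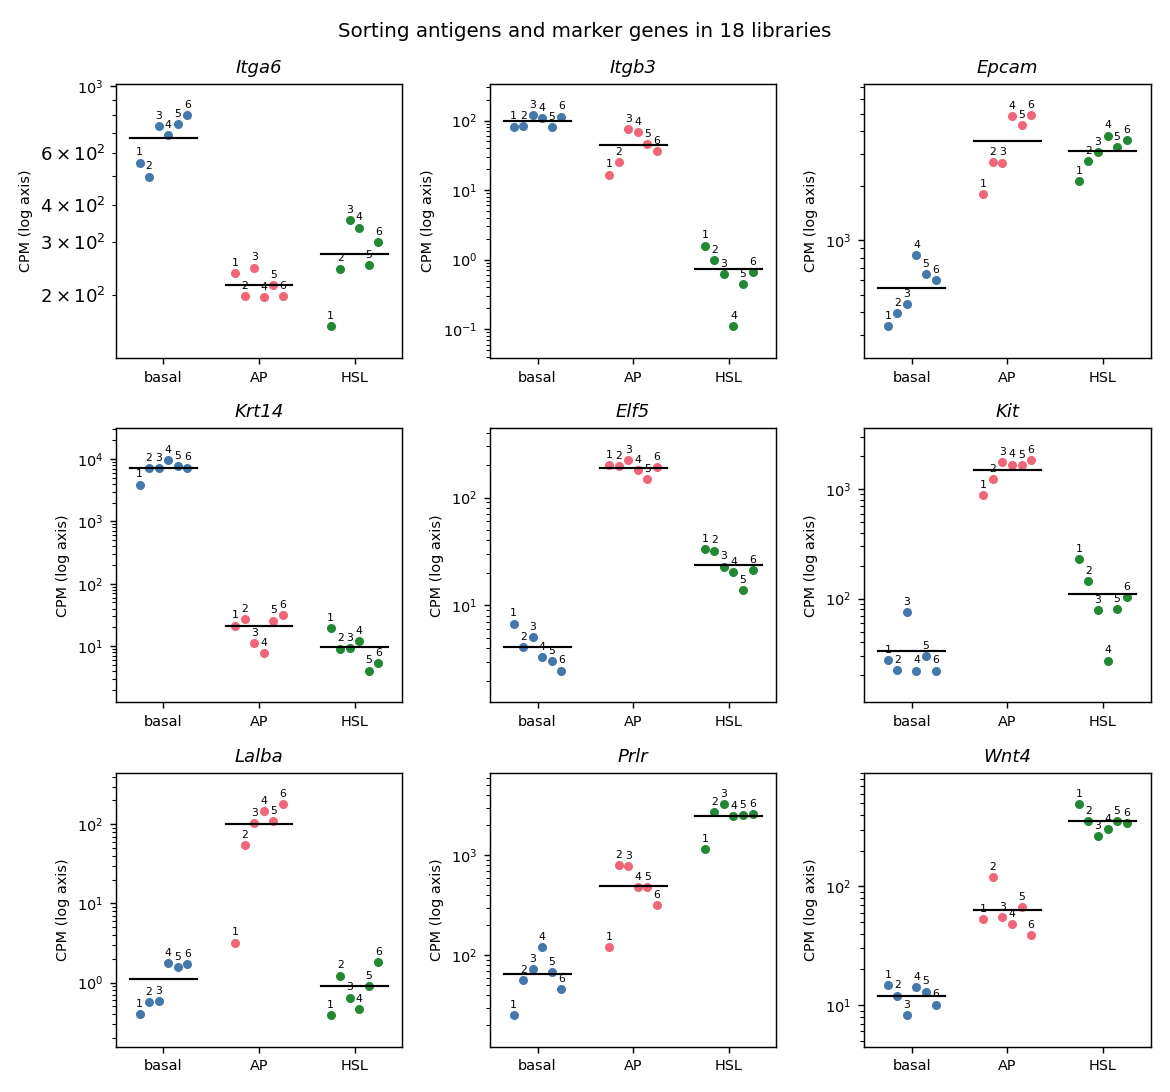
CPM (log axis) of 3 genes of the sorting antigens and 6 marker genes in each of the 18 libraries, by population; points are libraries, numbered by sample, and bars are means of 6. Itgb3 stood at 0.734 CPM on average in HSL libraries and at 44.6 in AP libraries.

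The first comparison asked how alveolar progenitors differ from basal cells. AP libraries carried luminal transcripts at higher levels and held the keratin and contractile transcripts of basal cells at lower levels. Lalba, the milk protein alpha-lactalbumin, was 89.8-fold higher in AP libraries, at 99.5 ± 63.1 CPM against 1.1 ± 0.646 in basal libraries (log2 6.49 ± 0.75, adjusted p = 1.23e-06). Elf5, a transcription factor of alveolar differentiation, was 46.1-fold higher (5.53 ± 0.28, adjusted p = 4.13e-11). Kit, a receptor tyrosine kinase that marks luminal progenitors, reached 1516 ± 377 CPM against 33.1 ± 21. In the other direction, Krt14, a basal keratin, fell from 7166 ± 1881 CPM in basal to 20.8 ± 9.45 in AP libraries (-8.43 ± 0.50, adjusted p = 3.36e-10). Acta2, smooth muscle actin, fell from 19110 ± 3872 to 61.6 ± 29.6 CPM. In GRCm38 coordinates Lalba (ENSMUSG00000022991) lies on chromosome 15, 98480400 to 98482721, Elf5 (ENSMUSG00000027186) on chromosome 2, 103411688 to 103450989, Kit (ENSMUSG00000005672) on chromosome 5, 75574916 to 75656722 and Krt14 (ENSMUSG00000045545) on chromosome 11, 100203162 to 100207548. None of these 4 genes shares its span with another gene.

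Of 16497 genes tested, 3548 were higher and 3813 lower in AP than in basal libraries, and 1996 and 2620 of these differed by at least 2-fold. The genes with the largest folds among those above 50 CPM and without overlap between libraries also included transporters. Slc28a3, a nucleoside transporter, was higher by 6.23 ± 0.67, Slc5a7, a choline transporter, by 5.80 ± 0.55, and Slc5a1, a sodium and glucose transporter, by 5.56 ± 0.50. Cck, which encodes cholecystokinin, was higher by 5.65 ± 0.43. Lower in AP libraries were Fmod (fibromodulin, -8.76 ± 0.56) and Krt5 (-8.44 ± 0.70), the partner keratin of Krt14.

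All 18 basal and myoepithelial markers were lower in AP libraries, with a median log2 fold change of -7.14 (adjusted p = 4.95e-22; adjusted p = 0.0216 with an estimated correlation), and all 18 were so when adjusted over the list alone. Snai2, a transcription factor of the basal lineage, was lower by -7.07 ± 0.31, and Sparc, a matrix glycoprotein, by -5.17 ± 0.30. All 17 measured smooth muscle contraction genes were lower as well (median -6.90, adjusted p = 2.39e-27; adjusted p = 0.0166 with an estimated correlation), among them Myl9 (-7.65 ± 0.35), Tpm2 (-8.05 ± 0.41) and Mylk (-7.70 ± 0.44), the kinase that activates myosin. Among basement membrane genes 15 of 18 were lower and 3 were not called (adjusted p = 3.29e-13; adjusted p = 0.0228 with an estimated correlation), with Col7a1 (-7.13 ± 0.41), Lamb1 (-3.71 ± 0.28) and Col4a1 (-3.64 ± 0.30) as examples. Integrin and hemidesmosome genes were lower in 11, higher in 1 and not called in 4 of 16 (adjusted p = 3.42e-05; adjusted p = 0.199 with an estimated correlation). Regulators of the epithelial-mesenchymal transition were lower in 7 of 11 (adjusted p = 0.00042; adjusted p = 0.266 with an estimated correlation).

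Luminal groups went the other way. Alveolar progenitor markers were higher in 13, lower in 1 and not called in 2 of 16 members (median 4.42, adjusted p = 8.1e-10; adjusted p = 0.16 with an estimated correlation). Cd14, a co-receptor for bacterial lipopolysaccharide, was higher by 4.64 ± 0.35 and Ehf, an epithelial transcription factor, by 5.40 ± 0.46. Of the pan-luminal markers 13 of 15 were higher (adjusted p = 6.04e-16; adjusted p = 0.0237 with an estimated correlation). Tight junction and apical polarity genes were higher in 13 of 16 (adjusted p = 3.67e-25; adjusted p = 0.00948 with an estimated correlation). Cldn3 (4.42 ± 0.17), Cldn7 (4.48 ± 0.23) and Ocln (4.44 ± 0.21) encode proteins of the junctions that seal the lumen. Milk protein and milk secretion genes were higher in 9 and lower in 1 of 12 (adjusted p = 0.000355; adjusted p = 0.199 with an estimated correlation), among them Btn1a1 (5.45 ± 0.59) and Plin2 (2.41 ± 0.28), which coat milk fat.

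Hormone-sensing luminal markers were higher in 13 and not called in 5 of 18 (adjusted p = 0.00118; adjusted p = 0.432 with an estimated correlation), for example Foxa1 (2.67 ± 0.24), a transcription factor that opens chromatin for the oestrogen receptor, and Prlr (2.94 ± 0.42), the prolactin receptor. A set of 12 of these markers was chosen after their values were seen. They were called, at least 16-fold higher in HSL than in basal libraries, and at a mean of 50 CPM or more in HSL libraries. Their median stood in the AP library of each sample at 11 to 33.2% of the level in its HSL library.

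Signalling lists were mixed. Wnt ligands, receptors and targets were lower in 14 and higher in 5 of 25 (adjusted p = 0.00774; adjusted p = 0.432 with an estimated correlation). Lgr5, a stem cell receptor for R-spondins, was lower by -6.84 ± 0.45 while the ligand Wnt7b was higher by 3.49 ± 0.17. The Notch ligands Dll1 (-6.09 ± 0.39) and Jag2 (-7.31 ± 0.53) were lower in a pathway list with 5 members higher and 5 lower of 15 (median 0.38, mean -0.36, adjusted p = 0.869 downward). EGF family ligands and receptors were higher in 8 and lower in 5 of 14 (adjusted p = 0.00848; adjusted p = 0.267 with an estimated correlation), with the receptor gene Erbb3 higher by 3.86 ± 0.25. Cholesterol synthesis genes were higher in 8 of 19 (adjusted p = 0.0108; adjusted p = 0.535 with an estimated correlation). No list-level call was made for steroid hormone and prolactin signalling (adjusted p = 0.227), innate defence (0.0529), interferon response (0.481), MHC class II (0.227), oxidative phosphorylation (0.953) or cell cycle genes (0.655). Of the 20 cell cycle genes 0 were called by edgeR (1 at an unadjusted p under 0.05, 0 by DESeq2, and 1 higher and 1 lower by limma-voom), and the mean of their log2 CPM was highest in sample 1 in each population, at 5.67 in its basal, 6.48 in its AP and 4.72 in its HSL library. Without sample 1 edgeR called 4 of them higher and 1 lower, and with the sample number as a block 9 higher and 1 lower.

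Markers of other cell types differed as well. All 12 endothelial markers were lower in AP libraries (adjusted p = 0.00454; adjusted p = 0.535 with an estimated correlation). All 4 measured erythroid markers were lower too (adjusted p = 0.0797, and 0.00176 with the sample number as a block; adjusted p = 0.535 with an estimated correlation and no block). Fibroblast markers went both ways, with 6 higher and 3 lower of 12 (median 1.06, adjusted p = 0.8). Col3a1, a fibrillar collagen, was at 516 ± 184 CPM in AP and 261 ± 53.1 in basal libraries (adjusted p = 0.0146). Its adjusted p was 0.0696 without sample 3, 0.0668 with samples 1 to 3 alone and 0.169 with samples 4 to 6 alone. Mmp2, a matrix protease, was at 37.7 ± 16.4 CPM in AP and 774 ± 300 in basal libraries. Pericyte markers were lower in 7 and higher in 1 of 10 (adjusted p = 0.227) and leukocyte markers lower in 3 of 11 (0.325). Adipocyte markers were lower in 1 of 5 (0.819) and Schwann cell markers higher in 3 and lower in 4 of 8 (0.8). Skeletal muscle markers (adjusted p = 0.966) and immediate early genes (0.227) were not called as lists. Adjusted over the list alone, the lists with other counts were basement membrane (16 lower), integrin (12 lower), milk (11 higher), cholesterol (10 higher), Notch (6 higher, 6 lower), hormone-sensing (1 lower), steroid hormone (5 lower) and interferon genes (1 higher against 4). They were also MHC class II (6 lower), innate defence (6 higher), fibroblast (7 higher), pericyte (8 lower) and leukocyte genes (0 lower).

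With total counts in place of scaling factors the median of all genes moved from -0.001 to 0.136, and the share of called genes that were higher from 48.2 to 57.6%. With only samples 1 to 3, treated here as a file series apart from samples 4 to 6, 3721 genes were called, and with samples 4 to 6 it was 7701. No label records a batch.

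The second comparison set hormone-sensing luminal cells against basal cells. HSL libraries held most hormone-sensing luminal markers at higher levels, and basal keratin and contractile transcripts at lower levels. The wider list of steroid hormone and prolactin signalling genes went both ways, as given below. Prlr reached 2449 ± 691 CPM against 65 ± 32.3 in basal libraries (log2 5.24 ± 0.47, adjusted p = 3.01e-08). Foxa1 was 30.9-fold higher (4.95 ± 0.27, adjusted p = 8.12e-11). Esr1, oestrogen receptor alpha, was 9.92-fold higher (3.31 ± 0.28, adjusted p = 1.55e-08). Krt14 fell to 9.76 ± 5.43 CPM (-9.51 ± 0.53, adjusted p = 8.8e-11). Cxcl14, a chemokine, fell from 3891 ± 1448 to 3.62 ± 1.16 CPM. Prlr (ENSMUSG00000005268) lies on chromosome 15, 10177238 to 10349180, Foxa1 (ENSMUSG00000035451) on chromosome 12, 57540628 to 57546916 and Esr1 (ENSMUSG00000019768) on chromosome 10, 4611593 to 5005614.

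Of the 16497 genes, 4593 were higher and 5041 lower in HSL than in basal libraries, with 2549 and 3616 of these at least 2-fold apart. Besides Prlr, the genes with the largest folds among those higher, above 50 CPM and without overlap between libraries included Proc (protein C, 5.49 ± 0.50), Ctse (cathepsin E, 5.31 ± 0.62), Agtr1a (an angiotensin receptor, 5.30 ± 0.43), Ffar4 (a fatty acid receptor, 5.24 ± 0.31), Capn8 (5.22 ± 0.39) and Hp (haptoglobin, 5.21 ± 0.41). Slc5a5, the sodium and iodide transporter, reached 3593 ± 1721 CPM against 101 ± 67.1. Among the lower genes were the cytokine gene Il17b (-10.24 ± 0.71), Fmod (-10.09 ± 0.60) and Cnn1, a smooth muscle calponin (-9.61 ± 0.61).

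Hormone-sensing luminal markers were higher in 16 of 18, and in 17 when adjusted over the list alone (median 4.84, adjusted p = 1.53e-09; adjusted p = 0.0896 with an estimated correlation). Wnt4, a Wnt ligand downstream of the progesterone receptor, was higher by 4.87 ± 0.27. Pan-luminal markers were higher in 14 of 15 (adjusted p = 4.55e-12; adjusted p = 0.0444 with an estimated correlation), with Krt19 at 4.51 ± 0.33 and Spint1, a protease inhibitor, at 2.95 ± 0.17. Tight junction genes were higher in 12 of 16 (adjusted p = 3.78e-14; adjusted p = 0.0166 with an estimated correlation), including Cldn8 (4.55 ± 0.20) and Marveld3 (3.44 ± 0.15). Oxidative phosphorylation genes were higher in 11 of 19 (adjusted p = 0.0487, 0.0504 with the sample number as a block, 0.0844 with total counts; adjusted p = 0.75 with an estimated correlation), by small amounts such as 0.83 ± 0.14 for Cox7a2. Cholesterol synthesis genes were higher in 10 and lower in 1 of 19 (adjusted p = 0.0164; adjusted p = 0.535 with an estimated correlation), with Sc5d at 1.57 ± 0.16 and Sqle at 1.77 ± 0.22.

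All 18 basal markers (adjusted p = 5.4e-20) and all 17 smooth muscle genes (adjusted p = 1.75e-22) were lower in HSL libraries, as were 16 of 18 basement membrane genes (adjusted p = 2.79e-14). With an estimated correlation each of these 3 lists had an adjusted p = 0.0166. Myl9 was lower by -8.57 ± 0.37, Acta2 by -9.32 ± 0.55, Col4a1 by -6.20 ± 0.34 and Col7a1 by -7.27 ± 0.41. Integrin and hemidesmosome genes were lower in 12 of 16 (adjusted p = 0.00169; adjusted p = 0.432 with an estimated correlation), with Itgb8 at -4.64 ± 0.34. Wnt genes were lower in 16 and higher in 5 of 25 (adjusted p = 0.00538; adjusted p = 0.272 with an estimated correlation), with Lgr4, a receptor for R-spondins, at -3.17 ± 0.14. Regulators of the epithelial-mesenchymal transition were lower in 10 of 11 (adjusted p = 5.06e-05; adjusted p = 0.196 with an estimated correlation), led by Snai2 (-7.61 ± 0.32).

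Alveolar progenitor markers were split, with 7 higher and 6 lower of 16 (adjusted p = 0.869): Elf5 was higher by 2.54 ± 0.24, while Lcn2, an iron-binding defence protein, was lower by -3.91 ± 0.41. The median of this list was 1.08, its mean -0.14, and the direction of the test was down. No call at the list level was made for milk (adjusted p = 0.869), Notch (0.16), interferon (0.884), MHC class II (0.712), innate defence (0.595, tested down with a median of 0.53 and a mean of -0.37) or cell cycle genes (0.693). Steroid hormone and prolactin signalling genes were higher in 8 and lower in 6 of 16 (adjusted p = 0.0825, and 0.00527 with the sample number as a block; adjusted p = 0.432 with an estimated correlation and no block), with Stat5a at 2.00 ± 0.13 and the glucocorticoid receptor gene Nr3c1 at -2.14 ± 0.18. EGF family genes gave an adjusted p = 0.0711, and 0.0149 with the block (adjusted p = 0.432 with an estimated correlation and no block), with Erbb2 at 2.49 ± 0.12 and Egfr at -4.28 ± 0.39.

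Fibroblast markers were lower in 11 of 12 (adjusted p = 7.42e-06; adjusted p = 0.199 with an estimated correlation). Endothelial markers were lower in 10 of 12 (adjusted p = 0.0146; adjusted p = 0.541 with an estimated correlation). Erythroid markers were lower in all 4 measured (adjusted p = 0.0809, and 0.00222 with the block; adjusted p = 0.535 with an estimated correlation and no block). Dissociation and immediate early genes, which respond to tissue handling, were lower in 13 and higher in 3 of 20 (adjusted p = 0.00876; adjusted p = 0.535 with an estimated correlation). Pericyte markers were lower in 9 of 10 (adjusted p = 0.0809), Schwann cell markers in 6 of 8 (0.202), leukocyte markers in 3 of 11 (0.403) and adipocyte markers in 2 of 5 (0.336), with no call for these lists or for skeletal muscle markers (0.884, tested up with a median of -0.57 and a mean of -0.31). Adjusted over the list alone, other counts were found for alveolar progenitor markers (8 higher), Wnt (6 higher), Notch (10 lower), epithelial-mesenchymal (11 lower), steroid hormone (9 higher), innate defence (6 higher), cell cycle (1 lower) and leukocyte genes (0 lower). Of the 20 cell cycle genes 1 was higher and 2 were lower, and without sample 1 edgeR called 3 higher and 14 lower, as it did with the sample number as a block.

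With only samples 1 to 3 the comparison called 5682 genes, and with samples 4 to 6 it called 9851.

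The third comparison set the luminal populations against each other. Most hormone-sensing luminal markers were higher in HSL libraries, and most milk, defence and progenitor transcripts were higher in AP libraries. Foxa1 was 4.86-fold higher in HSL libraries (log2 2.28 ± 0.24, adjusted p = 1.22e-06) and Wnt4 5.52-fold higher (2.46 ± 0.24, adjusted p = 6.01e-07). Lalba was lower in HSL libraries by -6.82 ± 0.77 (adjusted p = 2.39e-06), Elf5 by -2.99 ± 0.24 (adjusted p = 1.46e-07) and Cd14 by -3.95 ± 0.34 (adjusted p = 2.04e-07).

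Of the 16497 genes, 3261 were higher and 3319 lower in HSL than in AP libraries, with 1395 and 2221 at least 2-fold apart. The folds were not alike in the 2 directions. Genes at least 16-fold higher in HSL than in basal libraries stood in AP libraries at a 1st percentile of 7.15 to 18.2% of their HSL level. In the reverse direction this percentile was 13.2% in sample 1 and 0.364 to 3.48% in samples 2 to 6. Whether HSL-type cells in the AP gate made the folds of HSL over AP smaller was not tested. Among called genes above 50 CPM whose libraries did not overlap between the populations, the largest folds of HSL over AP included those of Agtr1a (2.70 ± 0.38), Arg1 (arginase, 2.68 ± 0.35) and Cldn6 (2.57 ± 0.30). The largest folds of AP over HSL included those of Lalba, Chil1 (-5.94 ± 0.57), Agt (angiotensinogen, -5.26 ± 0.53), Slc28a3 (-5.24 ± 0.64) and Lbp, the lipopolysaccharide-binding protein (-5.04 ± 0.42).

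Hormone-sensing luminal markers were higher in 16 of 18, with a median of 2.31 (adjusted p = 8.1e-10; adjusted p = 0.0542 with an estimated correlation). Esr1 was at 325 ± 51.5 CPM in HSL and 79.4 ± 29.1 in AP libraries (adjusted p = 1.15e-05, and 0.0563 with samples 1 to 3 alone), and Tbx3, a transcription factor, at 342 ± 43.1 and 91.1 ± 29.8. Within single samples, 12 markers were compared that were called, at least 16-fold higher in HSL than in basal libraries and at a mean of 50 CPM or more in HSL libraries. Tnfsf11, which encodes the RANK ligand, met that mean through sample 1 alone (592 CPM, against 0.132 to 6.33 in the other HSL libraries). The 12 stood in the AP library at a median of 11, 33.2, 23.3, 15, 19.4 and 12.5% of their HSL level in samples 1 to 6. For the prolactin receptor gene Prlr these shares were 10.4, 29.7, 23.9, 19.4, 19.1 and 12.3%, and for Foxa1 they were 11.3, 28.4, 23.8, 25.6, 19.7 and 14.4%.

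**Figure D2:**
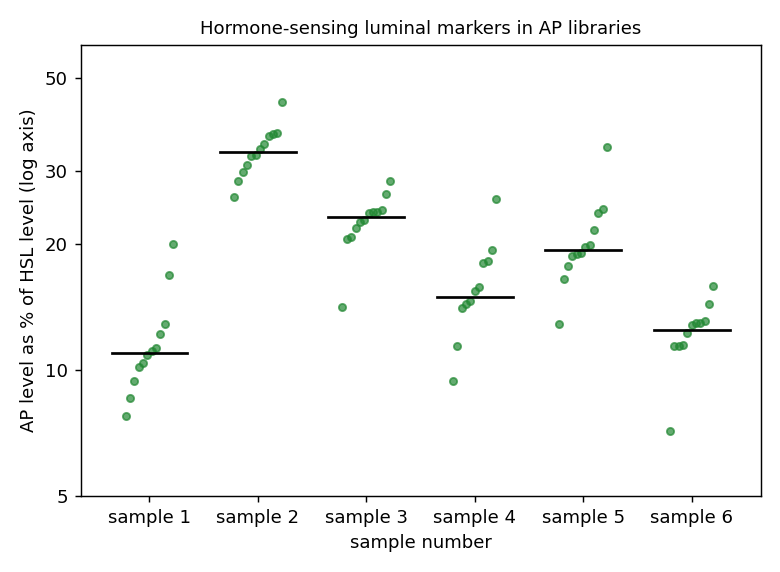
Level in the AP library as a percent of the level in the HSL library of the same sample (log axis), for 12 hormone-sensing luminal markers (points; values of 0 are left out) and their median (line), in samples 1 to 6. The medians ran from 11% in sample 1 to 33.2% in sample 2, and the values of 0 were those of Tnfsf11 in samples 4 and 6.

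Alveolar progenitor markers were lower in HSL libraries in 14 of 16 (median -3.50, adjusted p = 1.67e-18; adjusted p = 0.0166 with an estimated correlation). Foxc1, a transcription factor, was lower by -3.73 ± 0.29, and Mfge8, a milk fat globule protein, stood at 810 ± 492 CPM against 10640 ± 2587. Milk genes were lower in 11 of 12 (adjusted p = 9.45e-06; adjusted p = 0.0444 with an estimated correlation), including Xdh (-4.06 ± 0.44) and Btn1a1 (-4.56 ± 0.57). Innate defence genes were lower in 9 and not called in 4 of 13 (adjusted p = 0.000226, and 0.111 with an estimated correlation), with Lcn2 at -4.64 ± 0.42 and Tlr2 at -2.62 ± 0.28. Of this list, Lcn2, Ltf and Cd14 are also alveolar progenitor markers, and Pigr is also in the milk list. Notch genes were lower in 7 and higher in 2 of 15 (adjusted p = 0.0483, 0.112 with the sample number as a block, 0.0763 with total counts; adjusted p = 0.432 with an estimated correlation). The target gene Hey1 was lower by -4.43 ± 0.39 and the receptor gene Notch1 by -1.62 ± 0.23, while the ligand gene Jag1 was higher by 2.25 ± 0.24.

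Basement membrane genes were lower in 12 and higher in 2 of 18 (adjusted p = 0.000173; adjusted p = 0.199 with an estimated correlation), with Lama4 at -3.31 ± 0.35. Basal markers were lower in 9 of 18 (adjusted p = 0.00169; adjusted p = 0.458 with an estimated correlation). Smooth muscle genes were lower in 8 of 17 (adjusted p = 0.00656; adjusted p = 0.535 with an estimated correlation). Tagln, which shares 58% of its span with other genes, was at 4.85 and 1.46 CPM in AP and HSL libraries. Oxidative phosphorylation genes were higher in 11 of 19 (adjusted p = 0.00104; adjusted p = 0.535 with an estimated correlation). Fibroblast markers were lower in HSL libraries in 11 of 12 (adjusted p = 1.23e-13; adjusted p = 0.0444 with an estimated correlation), with Col3a1 at -4.11 ± 0.35. Immediate early genes were lower in 12 and higher in 4 of 20 (adjusted p = 0.0118; adjusted p = 0.535 with an estimated correlation).

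No list-level call was made between the luminal populations for pan-luminal markers (adjusted p = 0.696), integrins (0.865, tested up with a median of 0.30 and a mean of -0.38), Wnt genes (0.256), regulators of the epithelial-mesenchymal transition (0.0529), tight junctions (0.151), EGF family (0.8), cholesterol synthesis (0.668), interferon (0.293) or MHC class II genes (0.408). Steroid hormone and prolactin signalling genes gave an adjusted p = 0.119, and 0.00702 with the sample number as a block (adjusted p = 0.432 with an estimated correlation and no block). Cell cycle genes had a median of -1.91 and an adjusted p = 0.198 for the list, which was 0.000205 with the block. The correlation between these genes was estimated at 0.873, well above the preset 0.01, and with the estimated correlation, without the block, the list had an adjusted p = 0.932. Of the 20, edgeR called 0 (3 lower at an unadjusted p under 0.05, 2 lower by DESeq2 and 1 higher by limma-voom), but without sample 1, or with the sample number as a block, it called 16 lower in HSL libraries and 1 higher. Endothelial (adjusted p = 0.8), pericyte (0.202), leukocyte (0.947, tested down with a median of 0.07 and a mean of -0.10), erythroid (0.646), adipocyte (0.274), Schwann cell (0.122) and skeletal muscle markers (0.81) were not called as lists. Adjusted over the list alone, other counts were found for alveolar progenitor (15 lower), smooth muscle (12 lower), basement membrane (3 higher, 13 lower), integrin (6 higher), Wnt (7 higher, 11 lower), oxidative phosphorylation (12 higher), innate defence (2 higher), immediate early (13 lower) and Schwann cell genes (5 lower).

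With total counts in place of scaling factors the median of all genes moved from -0.011 to -0.185, and the share of called genes that were higher in HSL libraries from 49.6 to 35.6%. With only samples 1 to 3 the comparison called 1494 genes, and with samples 4 to 6 it called 7092. Of the 1494 with samples 1 to 3, 444 were higher in HSL libraries and 1050 lower (29.7% higher), against 47.7% higher with samples 4 to 6.

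Across the comparisons, 2999 genes were higher and 2606 lower in basal libraries than in both luminal populations, 2288 were higher and 2288 lower in HSL than in both others, and 966 were higher and 776 lower in AP, the last of which was 511 without sample 6 and 1186 with the sample number as a block. Independent lists of these sizes would overlap by 1170 and 988 genes for basal, 908 and 1010 for HSL, and 714 and 754 for AP. In 20 simulations of unchanged groups against the shared libraries the overlap of edgeR calls was 0, and on average between 64.4 and 99.8 genes at an unadjusted p under 0.05. With no gene changed, hardly any calls are made that could overlap. These values therefore do not measure what the shared libraries add to the overlap where many genes differ. With the shared libraries split by odd and even sample number the counts were 2497 and 2061 for basal, 1618 and 1899 for HSL, and 802 and 420 for AP. Independent lists of the sizes called in these split comparisons would overlap by 849 and 664, 528 and 780, and 497 and 331 genes.

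Milk protein genes, Csn3 aside, took a small share of the counts of these nulliparous glands. The 8 genes fixed for this measure held 0.0116 ± 0.00613% of counts in AP, 0.000141 ± 5.89e-05% in basal and 0.000158 ± 0.00014% in HSL libraries (SD, n = 6). Pooled over the libraries of a population, Lalba alone made up 91.1% of these counts in AP, 80.3% in basal and 48% in HSL. The pooled HSL value leans on sample 1, whose HSL library held 205 of these counts, against 24 to 58 in the others. Lalba was lowest in that library, at 0.388 CPM against 0.462 to 1.81. In the AP library of sample 1 it stood at 3.2 CPM, against 55.1 to 179 in the other AP libraries. The AP share was above every basal and HSL value in 6 of 6 libraries, and differed from both by exact two-sided permutation (p = 0.00216, the smallest it can give with 6 against 6; adjusted p = 0.00325 over 3 comparisons). The HSL and basal shares differed by less than the spread between libraries (exact permutation p = 0.872, adjusted p = 0.872), by 1.65e-05 percentage points, and by -2.71e-05 without sample 1. Per library the AP share ran from 0.0033% (95% Wilson interval 0.00314 to 0.00347%) in sample 1 to 0.0202% (0.0197 to 0.0206%) in sample 6, intervals that cover counting error only. Csn3, which encodes kappa-casein and lies within the span of another gene, is listed at 0 in all libraries and so adds nothing to the share. Its level cannot be judged from these counts, so the full share may be larger and the part of Lalba in it smaller.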

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

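The tests of the explanations for sample 1 were chosen only after its values were seen, while the measure of how far a library stands from its group and the regrouping of libraries were set beforehand.

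In 48 groups of 6 libraries whose means are printed, the highest or lowest library lay apart, by Dixon's 95% limit, in 4; chance gives about 1 in 20 groups. Kit was at 75.5 CPM in the basal library of sample 3, against 21.9 to 29.6 in the other basal libraries. In the HSL library of sample 1, Prlr was at 1160 CPM against 2480 to 3240 in the others, Ptprc at 17.7 CPM against 0 to 3.51, and the milk protein share at 0.000424% against 5.53e-05 to 0.000192%.

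Sample 1 stood apart from the other samples in all 3 populations. When it had its own term in the model, which took its 3 libraries as independent, 4579 genes were called for it. Its HSL library held Tnfsf11, which encodes the RANK ligand, at 592 CPM against 0.132 to 6.33 in the others, and Calca, which encodes calcitonin, at 2620 CPM against 0.286 to 13.9. A swap between populations is argued against, since 0 of its 3 libraries had their highest median correlation with another population. But its HSL library held more alveolar transcripts than the other HSL libraries (mean log2 CPM of the markers 6.03 against 3.57 to 4.93, Fcgbp at 2920 CPM against 105 to 609). Genes at least 16-fold higher in AP than in basal libraries stood in that library at a 1st percentile of 13.2% of their AP level, against 0.364 to 3.48% in samples 2 to 6. These values leave AP cells in the gate of that library open, and no prediction was set for them. Leukocyte and antigen-presenting transcripts were high in that library, with Cd74 at 612 CPM against 7.13 to 115 in the other HSL libraries, but as the source of Tnfsf11 they are argued against by the basal library of sample 1, which held Cd74 at 733 CPM and a higher mean log2 CPM of the leukocyte markers (3.97 against 3.06) with Tnfsf11 at 11.9 CPM; leukocytes of another kind in the HSL gate, which excluded CD45, stay open. A progesterone-exposed stage in this animal may account for the difference of sample 1. It was the highest in 6 of 6 measures (3 cell cycle scores and the HSL levels of Tnfsf11, Wnt4 and Calca), but these were picked after being seen. The progesterone receptor gene Pgr was lowest there among the HSL libraries (97.3 CPM against 341 to 532), a value for which no direction was predicted. No hormone measure or group in the design tests such a stage, so it stays untested.

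The counts of called genes were set against those of other splits of the libraries, where 1 of 100 is the smallest share possible. In a model of the 12 libraries compared, the real split called 7154 genes for AP against basal, and 1 of 100 splits called as many, the real one, with 1964 the highest of the others. For HSL against basal the real split called 9345 (1 of 100, highest other 990) and for HSL against AP 6402 (1 of 100, highest other 735). Those highest other splits had 5 of 6 libraries of a side from the same population. Of the splits drawn, 7 parted all 6 pairs as the real split does, and each of these called 0 genes by edgeR, with a median of 41, 63 and 59 genes at an unadjusted p under 0.05 in the 3 comparisons. Like every split but the real one, they mix both populations on each side, which widens the spread within a side. Fewer calls in them follow from the design, so the splits cannot exclude chance. DESeq2 and limma-voom were not run on the splits.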

How the results depend on the processing

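The alternative without genes that share much of their span was chosen after seeing the data; it and all others not named here left each count of called genes within 1.5 times its value. With samples 1 to 3 alone, fewer genes were called (3721 for AP against basal, 5682 for HSL against basal, 1494 for HSL against AP, and 1312 of these at least 2-fold), while samples 4 to 6, as many libraries, called 7701, 9851 and 7092. Samples 1 to 3 include sample 1, without which 8361, 10663 and 7910 genes were called. These counts were above those with all samples, while leaving out any other sample gave fewer. The cause was not tested. Testing against a fold of 1.5 gave 4358, 6264 and 3132, and the strict filter, which tests fewer genes, left 2508, 3305 and 2064 at least 2-fold. Genes above both other populations numbered 293 for AP, 1672 for basal and 295 for HSL with samples 1 to 3, and genes below both 120, 1214 and 694. With both folds at least 2 there were 568 higher and 317 lower in AP, 1341 lower in basal and 903 higher in HSL. The 776 lower in AP became 504 with total counts and 1186 with the sample number as a block, and 511 to 956 with 1 sample left out. The lists and the cell cycle counts that the block changed are given with them; it moved no other count by over 1.5 times and changed no call of a named gene, and the cause was not tested. Lists called fell from 14, 14 and 11 to 5, 5 and 3 with an estimated correlation, and rose to 23 for HSL against basal and 19 for HSL against AP with fry. Lists without a call changed direction for oxidative phosphorylation in AP against basal (adjusted p = 0.872) and leukocyte markers in HSL against AP (0.804) with total counts, and, with the block, for Schwann markers in AP against basal (0.944), alveolar markers in HSL against basal (0.936) and EGF genes in HSL against AP (0.918). The milk share of HSL less basal ran from -2.71e-05 to 4.13e-05 percentage points with 1 sample left out, and turned without sample 1. Of the 300 called gene results the naming rule allows, 235 kept call and direction in each of the 35 alternatives that tested them, and 65 did not. A gene that an alternative did not test was counted as kept there. The genes printed were chosen from the firmer ones. The depth lets a count of 0 stand for up to 0.0329 to 0.113 CPM per library.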

Other observations

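The tests of the patterns in this part were all chosen only after the results were seen.

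In the AP libraries, hormone-sensing transcripts stood above a floor, relative to their HSL level, that differed between samples. Over genes called and at least 16-fold higher in HSL than in basal libraries, at 50 CPM or more, and at 20 CPM or more in the HSL library of the sample, the 1st percentile of the AP to HSL ratio was 7.15, 18.2, 17.9, 10.2, 12.2 and 8% in samples 1 to 6 (the lowest 7.15%), the median 17, 33.4, 25.5, 18.3, 22.8 and 15%, and the 75th percentile 33.7, 43.2, 34.2, 28.2, 33.5 and 26.7%, so that many genes lay well above the floor. In the reverse direction, genes called and at least 16-fold higher in AP than in basal libraries stood in the HSL library of sample 1 at a 1st percentile of 13.2% and a median of 33.8% of their AP level, against 0.364 to 3.48% and 5.74 to 14.5% in samples 2 to 6. RNA or reads carried alike between all libraries are argued against by the basal markers, whose median stood in AP libraries at 0.705% of its basal level. Separate regulation of each marker is argued against by the shared order of the samples over 12 markers. Kendall's W was 0.83 (permutation p = 1e-05, the smallest that 100000 permutations can give), with Tnfsf11, low outside sample 1, among the 12. HSL-type cells inside the AP gate, which CD61 should exclude, may set this floor, while a hormone-sensing programme shared by the AP cells themselves stays open and was not tested.

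Fibroblast transcripts were present in the AP libraries, with Col3a1 at 317 to 758 CPM and Col1a1 at 46.3 to 231 CPM. Of the 12 markers 0 are in another list, and 5 stood at 50 CPM or more in basal libraries, among them Mmp2 at 774 CPM against 37.7 in AP libraries. Basal cells carried into the AP gate are argued against, as the median of 12 fibroblast markers stood in AP libraries at 209% of its basal level, while the basal markers stood at 0.705%. Stromal cells inside the AP gate may be their source, as the 12 markers rose and fell together over the 6 AP libraries (median pairwise Pearson r = 0.882, Spearman 0.771, permutation p = 1e-04, the smallest that 10000 permutations can give; r = 0.701 without samples 2 and 3), although EpCAM was among the sorting antigens. Expression of these genes by AP cells themselves stays open and was not tested.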
